A study of Homo sapiens with 9 samples.

How the data were processed

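Right ventricular tissue of patients with ARVC was frozen in liquid nitrogen, total RNA was extracted with Trizol, and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. The labels name this kit for all samples, and whether it marked the strand of the RNA is not established here. The table analysed holds a normalised signal per gene: per its name, the authors deposited read counts normalised by DESeq2, with 1 column for each of 9 samples. TopHat2 2.1.1, Cufflinks 2.2.1, DESeq2 and the human genome build hg19 are named in the submitters' processing notes, with no role or order. The counting tool, its strand setting, the gene annotation and the filters are not given in the sources used here.

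In each column the deposited signal values were whole multiples of 1 step, the reciprocal of that sample's size factor. Dividing by the step gave whole reads for 100% of values in every sample at a tolerance of 0.02, and the recovered totals were 35973529 to 92355167 gene reads per sample. These totals count reads on listed genes only. At this depth counting error is small against the spread between samples, and intervals cover counting error only.

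Of 25369 entries, 28 bore dates in place of gene symbols, as spreadsheet programs write them, and were left out. A further 177 were left out because they can point to a person: X-inactivation and Y-linked genes, HLA genes, immunoglobulin and T cell receptor segments, and genes with common deletion or null alleles. The rule for this was set before the data were examined, and some genes were added to it after their values had been seen. For 2 list genes with known copy number or deficiency alleles, no level of a single sample is given, which was also decided after seeing the values. Gene types, GC content, length and overlaps came from GENCODE and RefSeq annotations of GRCh38, a later build than hg19, so no coordinates are given. Of the entries, 23383 (92.9%) matched GENCODE by symbol, and 95.7% of those with a mean of at least 10 had a GC value.

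All samples were in 1 group, so no group comparison and no blocking by replicate applied. The lists, scores, tests, named-gene rule and most other settings were fixed before the data were examined. Values were tested as log2(value + 1), with genes of a mean of at least 10. Slopes on log2(value + 1) understate changes of low genes. Each of 3 scores was the mean of the z-scored log2 values of its markers, scaled to an SD of 1, and its markers were left out of its tests. Genes were regressed on a score with limma 3.58.1 (lmFit and eBayes with a trend, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Lists with at least 4 members were tested by limma's camera with a preset correlation of 0.01, again with an estimated correlation, and by fry, adjusted over the 30 lists of a score. A list adjusted over the list alone used the p-values of its members only. The test planned for normalised values was kept, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on recovered reads as alternatives.

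List scores were the mean z over members, with genes in both lists of a pair left out. Pearson's r and Spearman's rho had exact two-sided permutation p-values over all 362880 orders of 9 samples, adjusted over 45 pairs. Ratios of paired genes were tested by exact sign flips over 9 samples. The spread of a list was the median SD of its members, ranked among 10000 random lists matched in size and in 20 bins of mean expression. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used.

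In all, 31 lists of 375 genes were fixed, of which 362 genes were analysed. Genes were named by rule: per score the 10 smallest p in each direction among those passing with a mean of at least 50, or the 3 nearest to passing where none did; per list the highest means and the largest SD; the 12 most variable genes with a mean of at least 100; the 10 most abundant; every desmosome, other cardiomyopathy and long non-coding RNA list gene; and both genes of each pair. Some genes and a pair that this rule takes are not reported here. Score markers were named too, and genes outside the rule are said to be chosen after their values were seen.

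The library sets were defined after seeing the data, from reads on nested opposite-strand genes (under 4 per 10000 reads for samples 3 to 5) and total reads. Nested genes lay to at least 90% inside a gene on the opposite strand with at least 10 times their reads. The 3 sets, a per-sample correction for GC content and length, and the 6 samples outside samples 3 to 5 were used in alternatives added after seeing the data. Every test of a technical explanation, and every criterion for it, was written down after its result had been seen.

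Other settings, fixed before the data were examined, were pseudocounts of 0.5 and 8, no filter and a mean of at least 100, rescaling to the same total, by TMM factors and by reference genes, scores of 1 marker, total reads as a covariate, other tools, and leaving out each sample or the 2 samples farthest from the median score. For each score, 100 random orders of its values over the samples, the real one included, were refitted. The limma step was tested on simulated counts for the real genes with 200 changed genes. Slopes of 0.5 per SD were recovered for 29.9% of changed genes on the adipocyte score (17518 genes), 32.8% on the collagen score (17539 genes) and 28.4% on the natriuretic score (17535 genes). Slopes of 1.0 were recovered for 100%, 100% and 98.5% in that order. False calls were 16 of 169, 11 of 166 and 12 of 163, each a share above 0.05. Genes were simulated independently with a single dispersion of 0.1, so these rates need not hold for real genes that vary together. With no relation simulated, 4.67% of permutation tests and 3.33% of sign-flip tests fell under 0.05.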

Results

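RNA sequencing of right ventricular tissue was available from 9 samples of patients with arrhythmogenic right ventricular cardiomyopathy (ARVC), an inherited disease in which heart muscle of the right ventricle is replaced by fat and scar. All 9 samples formed a single group, with no control heart, so no difference between patients and healthy tissue was tested. The title of the series names heart-specific long non-coding RNAs as its subject. The comparisons made were between genes within a sample and between samples along measured tissue axes. The labels describe samples from patients without tying each sample to its own patient. The p-values of single genes, paired ratios and correlations therefore measure the spread between these 9 samples. Camera p-values with the preset correlation of 0.01 do not measure that spread alone. They treat the genes of a list as almost independent, so they also depend on the number of genes. The estimated correlations of the lists ran from -0.02 to 0.89 over all scores.

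The 9 samples carried 39575935, 35973529, 74127414, 77942894, 69791020, 83799559, 86031597, 92355167 and 70291361 recovered gene reads, in the order of samples 1 to 9. Of 25164 gene entries analysed, 17635 had a mean normalised read count of at least 10. Spearman correlations between samples across genes ranged from 0.961 to 0.989, and no 2 columns agreed within counting noise (smallest chi-square per degree of freedom 96.0), a check for repeated columns that says nothing about patients. Samples 3, 4 and 5 stood apart on a technical measure: genes lying inside a more expressed gene on the opposite strand took 2.62 to 2.79 of every 10000 reads there, against 5.22 to 8.06 in the other 6 samples. The 95% Wilson intervals nearest to each other were 2.75 to 2.83 in sample 5 and 5.17 to 5.27 in sample 8, and they cover counting error only. Samples 1 and 2 were the shallowest. These 3 library sets (samples 1 and 2, samples 3 to 5, samples 6 to 9) were defined from the data and are not groups of the study.

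**Figure D1:**
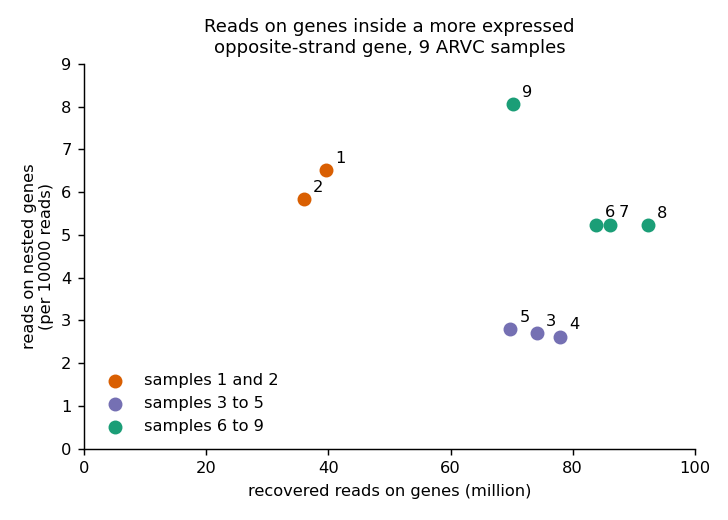
Reads per 10000 on genes lying inside a more expressed opposite-strand gene (vertical axis) against recovered gene reads (horizontal axis, scaled as labelled), 1 point per sample, numbered 1 to 9 and coloured by library set. Samples 3 to 5 lie between 2.62 and 2.79, and the other 6 samples between 5.22 and 8.06.

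TTN, which encodes the giant sarcomere protein titin, had the highest mean normalised read count, 4971800 ± 2260700 (SD, n = 9), or 8.40% of the deposited total on average. MYH7, the slow cardiac myosin heavy chain, followed at 1442800 ± 369230. The other 8 of the 10 most abundant genes were RPPH1 (mean 939980) and RMRP (mean 913460), the RNA components of RNase P and RNase MRP, the muscle genes DES (578420), ANKRD1 (365220), MB (332560) and TPM1 (308940), the long non-coding RNA MALAT1 (305750) and the translation factor EEF1A1 (284650). Read counts were not divided by gene length, so long genes such as TTN rank high partly by length.

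All 13 measured genes of the desmosome and intercalated disc, the cell junctions of heart muscle, were expressed in every sample. DSP, the desmosomal plaque protein desmoplakin, had a mean normalised read count of 43849 ± 13647 (SD, n = 9), and PKP2, the desmosomal gene most often mutated in ARVC, 27444 ± 4488 with a range of 19538 to 34541. The other desmosomal genes were lower: JUP at 4521 ± 1659, DSG2 at 4240 ± 1484 and DSC2 at 3677 ± 1100. PKP4, a related plaque gene, was at 4867 ± 642. Among the other junction genes, CTNNA1 was at 29749 ± 3303, CDH2 at 28003 ± 5508, VCL at 26517 ± 6870, CTNNB1 at 24666 ± 1763, GJA1 at 24479 ± 4957, CTNNA3 at 17778 ± 4053 and TJP1 at 15050 ± 2529. CTNNB1 varied least of the 13, with a coefficient of variation of 7.15%, and JUP most, with 36.7%.

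Genes of other inherited arrhythmogenic cardiomyopathies were also expressed in all 9 samples. Besides TTN and DES, the calcium release channel RYR2 averaged 272630 ± 113970 normalised read counts (SD, n = 9), PLN 136200 ± 30782 and FLNC 117980 ± 50708. LMNA averaged 15530 ± 2716, TMEM43 5463 ± 1087 and TGFB3 2640 ± 510.

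Of 25 long non-coding RNAs chosen before the data were examined, 22 were analysed and 21 of these had a mean of at least 10. MALAT1 was highest, followed by LINC00657 (NORAD) at 48219 ± 7656 (SD, n = 9), the imprinted H19 at 23625 ± 9601, NEAT1 at 10480 ± 5003, KCNQ1OT1 at 6171 ± 3569 and TUG1 at 5728 ± 1453. DANCR (1986 ± 338), MEG3 (1773 ± 1026), GAS5 (1426 ± 386), HAND2-AS1 (1201 ± 394), TTN-AS1 (1165 ± 479) and LINC00472 (991 ± 221) came next. The cardiac-enriched LINC00881 was at 692 ± 349, MIAT at 317 ± 142 and FENDRR at 1.86 ± 1.91. Between samples KCNQ1OT1 had an SD of 0.84 on the log2 scale, and of 0.47 within library sets. HAND2-AS1, TTN-AS1 and KCNQ1OT1 run antisense to coding genes, and the strand setting of the counting is not given in the sources used here, so their reads cannot be separated from those of their partners. Of 1123 long non-coding RNAs, 225 were lower and 2 higher by limma in samples 3 to 5, which were set apart by a technical measure.

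Paired genes within each sample asked how far the ventricular and adult forms of contractile and membrane genes outweighed their atrial, fetal or skeletal counterparts. MYH7 exceeded MYH6, the fast cardiac myosin, by 6.43 ± 0.63 on the log2 scale (SD, n = 9), a geometric mean ratio of 86.1-fold. The ventricular light chain MYL2 exceeded the atrial MYL7 by 4.05 ± 1.34, and the adult cardiac troponin TNNI3 exceeded the fetal TNNI1 by 6.33 ± 1.73. ATP2A2, the cardiac calcium pump SERCA2, exceeded the skeletal ATP2A1 by 11.36 ± 0.94, and the ventricular connexin GJA1 exceeded GJA5 by 3.80 ± 0.85. NPPA, which encodes the atrial natriuretic peptide, exceeded NPPB by 1.77 ± 0.54, and COL3A1 exceeded COL1A1 by 2.23 ± 0.59. Each of these 7 ratios was above 0 in 9 of 9 samples (two-sided exact sign-flip permutation p = 0.00391, the smallest 9 samples allow, adjusted p = 0.00502 over 9 pairs).

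DSG2 and DSC2, the desmosomal cadherin genes, differed by 0.19 ± 0.28 (SD, n = 9, higher DSG2 in 7 of 9 samples, exact permutation p = 0.0859, adjusted p = 0.0967), which did not pass. Without sample 8 this ratio was 0.25 and passed. The values were not divided by gene length, so a ratio between genes of unequal length is one of reads, not of molecules.

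**Figure D2:**
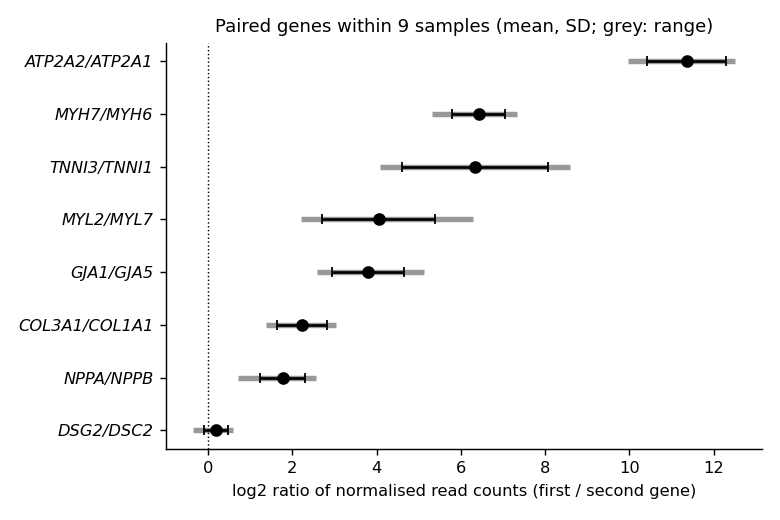
Log2 ratio of normalised read counts (horizontal axis) for 8 gene pairs in 9 samples, with points for means, black bars for the SD and grey bars for the range. The 7 pairs from ATP2A2/ATP2A1 (11.36) to NPPA/NPPB (1.77) lie above 0 in every sample, and DSG2/DSC2 (0.19) spans 0.

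Gene groups differed widely in how much they varied between samples. The adipocyte list had the largest spread, with a median SD of 1.85 on the log2 scale over 12 genes, against a median of 0.27 in random lists of matched expression. PLIN1, the coat protein of fat droplets, ranged from 400 to 17211 normalised read counts, and ADIPOQ, which encodes the fat hormone adiponectin, from 187 to 17826. PLIN4 ranged from 8340 to 42682, and FABP4, a fatty acid carrier of adipocytes and capillaries, from 2710 to 34998. The natriuretic and fetal stress list had a median SD of 1.08, and its member NPPA ranged from 9015 to 297820 while ANKRD1 stayed between 206300 and 461380.

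In all, 14 of 30 lists lay at or above percentile 97.5 of 10000 random lists of the same size and mean expression, a description across genes with no p-value over samples. Besides the adipocyte and natriuretic lists these were, by median SD, skeletal muscle markers (1.48), neutrophil and acute inflammation (1.01), atrial markers (0.80), fibroblast and collagen matrix (0.73), immediate early and heat shock (0.61), Wnt pathway (0.61), named long non-coding RNAs (0.55), adipogenic transcription factors (0.49), macrophage (0.45), calcium handling and ion channels (0.42), sarcomere (0.38) and TGF-beta pathway (0.37). COMP, a cartilage matrix protein, had the largest SD of the fibroblast list at 2.51, with a range of 21.5 to 10095. FOS (SD 1.35) and FOSB (SD 1.99) varied most among immediate early genes. FOSB lies inside a more expressed gene on the opposite strand, so its value is uncertain as a measure of that gene. Its SD within library sets was 2.12.

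The desmosome and intercalated disc list had a median SD of 0.29 (percentile 73.3, against 0.26 in random lists of matched expression), reference genes 0.26 (percentile 19.5) and the Hippo pathway 0.20 (percentile 10.9), with YAP1 at 7862 ± 935 (SD, n = 9). The lists between were interferon response (percentile 97.4), smooth muscle and pericyte (96.5), Schwann cell and neuron (96.2), endothelial (95.4), other arrhythmogenic cardiomyopathy genes (92.5), erythroid (91.6), proliferation (90.1), nuclear oxidative phosphorylation (88.5), lymphocyte (86.3), glycolysis (83.4), mesothelial and epicardial (81.4), mast cell (78.3) and fatty acid oxidation (77.2). With the SD taken within the library sets, 20 lists lay at or above percentile 97.5, and the median SD was 1.25 for adipocyte genes and 0.93 for skeletal muscle markers. The 9 mitochondrially encoded genes chosen beforehand were not analysed here.

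**Figure D3:**
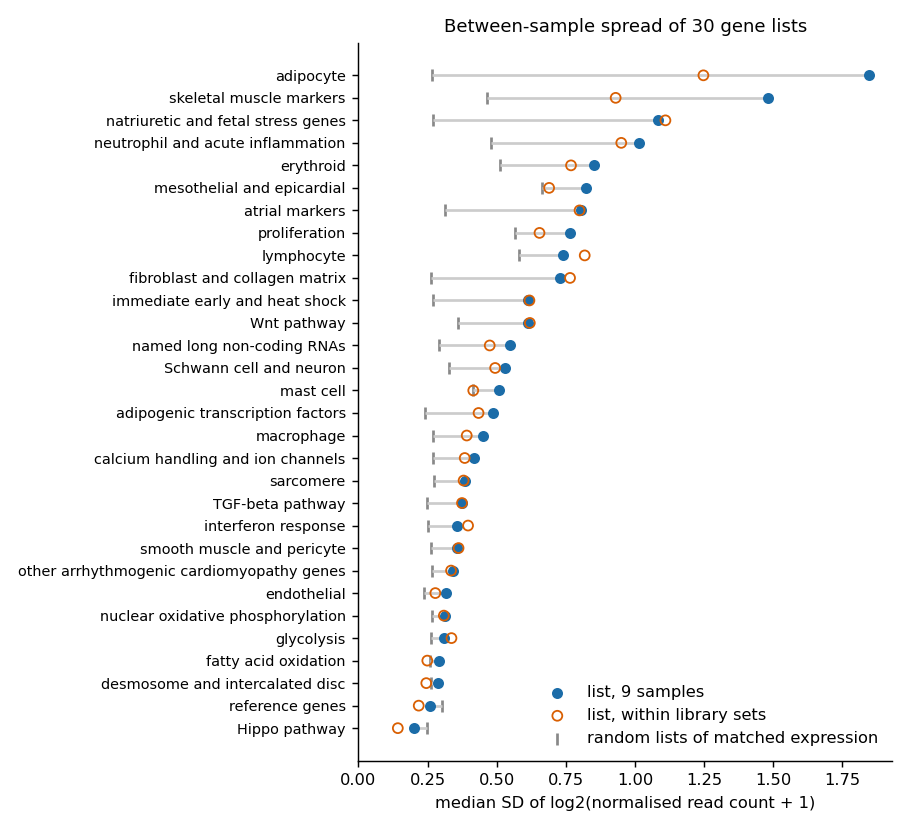
Median SD of log2(normalised read count + 1) over the members of 30 gene lists (horizontal axis), for 9 samples (filled points), within library sets (open points) and in random lists of matched expression (grey ticks). The adipocyte list is highest at 1.85 and the Hippo pathway lowest at 0.20.

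Single genes with the largest SD were mostly set apart by samples 3 to 5. Of the 12 most variable genes with a mean of at least 100, MIF, a cytokine expressed in most tissues, was listed at 0 in the other 6 samples and at 3837 to 4162 in samples 3 to 5, and HYI was listed at 0 in the other 6 and at 788 to 1066 in samples 3 to 5. The remaining 10 went the other way. CDR1 was at 0.77 to 3.21 in samples 3 to 5 and at 2498 to 11674 in the others, and LRRTM3 at 1.54 to 5.90 against 653 to 2282. ANKRD36BP1, CELF2-AS2 and LOC349160 were listed at 0 in samples 3 to 5, and MIRLET7DHG, C1orf192, TMEM14E, PLAC4 and LOC148696 at most at 8.43. Many of these entries lie within or across genes on the opposite strand, and their values are uncertain as measures of the named gene.

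Fat content was the first axis followed, because fatty replacement of muscle defines the disease. The adipocyte score, built from PLIN1, ADIPOQ, CIDEC, PLIN4 and GPD1, was lowest in sample 1 (-1.61) and highest in sample 8 (1.44). With it, 32 genes rose and 0 fell by limma at an adjusted p under 0.05 (739 genes at an unadjusted p under 0.05), against 33 and 0 by edgeR and 82 and 11 by DESeq2. LGALS12, an adipocyte galectin, rose by 2.31 ± 0.15 on the log2 scale per SD of the score (SE, n = 9, adjusted p = 0.000172). THRSP, a regulator of fat synthesis, rose by 2.27 ± 0.16 (adjusted p = 0.000222), and TF, which encodes the iron carrier transferrin, by 2.23 ± 0.17 (adjusted p = 0.000234).

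The next genes by p were PCK1 (2.29 ± 0.18), CIDEA (1.56 ± 0.12), TUSC5 (1.79 ± 0.14), KANK4 (1.22 ± 0.10), LOC101926960 (2.42 ± 0.21), GYG2 (1.81 ± 0.16) and RBP4 (1.95 ± 0.18), with adjusted p of 0.000234 to 0.000569 (slope ± SE, n = 9). PCK1 makes the glycerol backbone of stored fat, CIDEA and TUSC5 belong to fat droplets and to insulin-driven glucose uptake, and RBP4 is a secreted retinol carrier. SCD, the fat desaturase, which was chosen after its values were seen, rose by 1.96 ± 0.30 (adjusted p = 0.0288). Its normalised read count was 178640 in sample 8 and 1199 to 14098 in the other 8 samples. The genes nearest to passing in the lower direction were RRP12 (slope -0.54 ± 0.09, adjusted p = 0.0679), CD24 (-2.13 ± 0.42, adjusted p = 0.127) and CNTNAP3B (-0.53 ± 0.13, adjusted p = 0.376).

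Of the 7 adipocyte list genes outside the score, 5 rose over all genes tested (CIDEA, PCK1, TUSC5, and LIPE and LEP, which were named after their values were seen) and 7 when adjusted over the list alone. Their median slope was 1.56 (camera adjusted p = 1.36e-28, adjusted p = 0.00225 with an estimated correlation, and fry adjusted p = 3.91e-05). Of 11 adipogenic transcription factors, PPARG (0.64 ± 0.09) and CEBPA (1.11 ± 0.15), the central regulators of fat cell formation, the first of them named after its value was seen, rose over all genes tested, and the same number, 2, passed when adjusted over the list alone. The median slope of that list was 0.16 (camera adjusted p = 0.00244, but adjusted p = 0.316 with an estimated correlation). KCNIP2, a subunit of cardiac potassium channels and the member of the calcium handling and ion channels list with the largest SD, rose by 0.94 ± 0.12 (adjusted p = 0.00748), the 1 gene of its 18 members that passed.

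The macrophage list (12 genes, median slope 0.10, camera adjusted p = 0.0260) and the nuclear oxidative phosphorylation list (16 genes, median slope 0.08, camera adjusted p = 0.0260) had higher medians, and both had adjusted p = 0.776 with an estimated correlation. The desmosome and intercalated disc list had a lower median (-0.13, camera adjusted p = 0.00244, adjusted p = 0.776 with an estimated correlation), and none of its 13 members passed over all genes or when adjusted over the list alone. DSG2 had a slope of -0.33 ± 0.10 and JUP of -0.32 ± 0.11. With the library sets in the model these 3 medians changed sign and did not pass by camera, at -0.10 for macrophage genes (adjusted p = 0.0578), -0.013 for oxidative phosphorylation (adjusted p = 0.930) and 0.036 for the desmosome list (adjusted p = 0.700). In that model 4 lists passed, 2 of them shared with the 5, and the new ones were glycolysis (median slope 0.06) and Schwann cell and neuron (-0.31, against 0.12 without the sets), with adjusted p = 0.0399 each. After GC and length correction, chosen after seeing the data, oxidative phosphorylation did not pass either (adjusted p = 0.109). The other 25 lists did not pass by camera (adjusted p = 0.0656 to 0.817), among them fibroblast and collagen matrix (median slope 0.03) and sarcomere (0.05).

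The library sets explained 62.2% of the variance of the adipocyte score, which was lowest in the shallow samples 1 and 2. The score had r = 0.80 with total reads (exact permutation p = 0.00771, adjusted p = 0.139 over 18 relations; rho = 0.73, exact permutation p = 0.0311, adjusted p = 0.560) and r = 0.36 without samples 1 and 2, the farthest from the median of total reads, so the relation rests on those samples, and the sets held too few samples for a value within each. With the library sets in the model 11 genes passed, 10 of them shared with the 32. Of the genes named above, TUSC5 (adjusted p = 0.0577), KANK4 (0.0690), CEBPA (0.113), LEP (0.213), PPARG (0.497), SCD (0.563) and KCNIP2 (0.657) then did not pass. Their slopes in that model were 1.67, 1.21, 1.40, 1.55, 0.59, 2.24 and 0.77, in that order, so the call was lost with slopes near those above for some of them. With total reads in the model 3 genes passed. Without samples 1 and 8 the count was 7, without sample 8 it was 17 and without sample 2 it was 20.

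**Figure D4:**
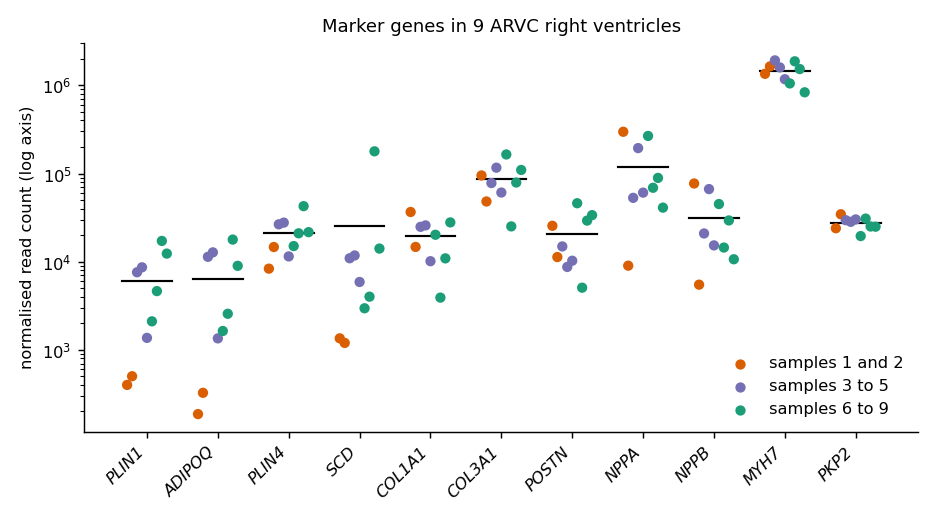
Normalised read counts on a log axis (vertical) of 11 marker genes (horizontal) in 9 samples, with 1 point per sample coloured by library set and a line at the mean. PLIN1 ranges from 400 to 17211 and NPPA from 9015 to 297820, while PKP2 stays between 19538 and 34541.

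The fibrous part of the tissue was followed by a collagen score built from COL1A1, COL1A2, COL3A1, LUM and POSTN. It was lowest in sample 7 (-2.06) and highest in sample 6 (1.32). With it, 9 genes rose and 0 fell by limma (1271 genes at an unadjusted p under 0.05), against 1 and 0 by edgeR and 152 and 58 by DESeq2. DDAH1, an enzyme that breaks down an inhibitor of nitric oxide synthesis, rose by 0.50 ± 0.05 on the log2 scale per SD of the score (SE, n = 9, adjusted p = 0.00735). The other 8 had an adjusted p of 0.0371: the matrix genes HAPLN1 (1.18 ± 0.16), MFAP5 (1.00 ± 0.14), COL5A2 (0.56 ± 0.08) and SRPX2 (0.69 ± 0.09), the protease inhibitor SERPINE2 (0.80 ± 0.10), the thrombin receptor F2R (0.62 ± 0.08), ZNF365 (0.89 ± 0.12) and MAP3K7CL (0.71 ± 0.10).

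Of the 13 fibroblast and collagen matrix genes outside the score, COL5A2 alone rose over all genes tested and 11 rose when adjusted over the list alone. Their median slope was 0.53 (camera adjusted p = 7.17e-19, adjusted p = 0.0108 with an estimated correlation, and fry adjusted p = 0.00322). FN1, the most abundant of them at 89765 ± 35809 normalised read counts (SD, n = 9), had a slope of 0.61 ± 0.11 (limma adjusted p = 0.0903), ASPN 0.88 ± 0.14 (limma adjusted p = 0.0517) and FAP, a marker of activated fibroblasts, 0.75 ± 0.12 (limma adjusted p = 0.0517), and ASPN and FAP were chosen after their values were seen. The TGF-beta pathway list also had a higher median (0.21, camera adjusted p = 3.00e-06), but adjusted p = 0.231 with an estimated correlation, and 0 of its 13 members passed over all genes and 5 when adjusted over the list alone. Its most abundant member LTBP2 had a slope of 0.78 ± 0.24.

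Muscle and metabolism lists had lower medians along the collagen score. They were sarcomere (median slope -0.22, camera adjusted p = 8.44e-08), nuclear oxidative phosphorylation (-0.19, 2.13e-08), glycolysis (-0.19, 9.06e-05), desmosome and intercalated disc (-0.16, 0.00275), calcium handling and ion channels (-0.15, 7.83e-05) and fatty acid oxidation (-0.15, 7.83e-05). With an estimated correlation these had adjusted p = 0.413, 0.488, 0.592, 0.594, 0.413 and 0.446, in that order. No member of these 6 lists passed over all genes tested or when adjusted over the list alone. LPL, which frees fatty acids from blood lipoproteins, had a slope of -0.43 ± 0.13, RYR2 of -0.41 ± 0.15 and PKP2 of -0.19 ± 0.07. The macrophage list had a higher median (0.15, camera adjusted p = 0.00575, adjusted p = 0.666 with an estimated correlation). The endothelial list had a median slope of -0.01 (camera adjusted p = 0.993) and the adipocyte list of 0.15 (camera adjusted p = 0.485), and with these included 21 lists did not pass by camera (adjusted p = 0.0872 to 0.993). The genes nearest to passing in the lower direction were PAIP2B (-0.44 ± 0.07, limma adjusted p = 0.0517), FITM2 (-0.34 ± 0.07, limma adjusted p = 0.112) and ASB11 (-0.40 ± 0.08, limma adjusted p = 0.120).

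The number of genes following the collagen score moved with single samples. It was 0 without samples 7 and 6, 14 without sample 2, 1 without any of samples 1, 3, 5, 7 or 9, 2 without sample 6 or 8, and 52 (45 higher, 7 lower, with all 9 shared) with the library sets in the model, where FN1 and ASPN (limma adjusted p = 0.0365 each), FAP, PAIP2B and ASB11 (limma adjusted p = 0.0472 each) also passed. Library sets explained 1.39% of the variance of this score.

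Natriuretic peptide genes rise under wall stress, and a score from NPPA and NPPB was the last axis. It was lowest in sample 2 (-1.84) and highest in sample 1 (1.32). No gene passed by limma (0 of the genes tested, with 856 at an unadjusted p under 0.05) or by edgeR (0), and DESeq2 called 7 higher and 11 lower. The genes nearest to passing were IGFBP2, a binding protein of insulin-like growth factors (0.72 ± 0.10 on the log2 scale per SD of the score, SE, n = 9, limma adjusted p = 0.416), NGFR (0.66 ± 0.12, limma adjusted p = 0.701) and ORAI2 (0.31 ± 0.07, limma adjusted p = 0.999). In the lower direction they were KIAA1244 (-0.55 ± 0.08, limma adjusted p = 0.416), DHRS7C (-1.94 ± 0.31, limma adjusted p = 0.450) and C1orf168 (-0.59 ± 0.10, limma adjusted p = 0.450).

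Of the lists, 4 had higher medians along the natriuretic score by camera: fibroblast and collagen matrix (0.35, adjusted p = 1.68e-06), immediate early and heat shock (0.24, adjusted p = 0.00753), neutrophil and acute inflammation (0.14, adjusted p = 0.0250) and macrophage (0.11, adjusted p = 0.0304). The desmosome and intercalated disc list (-0.12, adjusted p = 0.00753) and the calcium handling and ion channels list (-0.12, adjusted p = 0.0430) had lower medians. Both lean on sample 2, which had the lowest natriuretic score and the highest list scores of both (1.48 and 0.98). Sample 9, with the next lowest natriuretic score (-0.75), had the lowest list scores of both (-0.85 and -0.97). Sample 2 also had the lowest macrophage list score (-1.08). None of the 6 held with an estimated correlation (adjusted p = 0.796 to 0.951) or by fry (adjusted p = 0.944). No member of any list passed over all genes tested or when adjusted over the list alone. The remaining 8 natriuretic and fetal stress genes had a median slope of 0.19 (camera adjusted p = 0.696), and 24 lists in all did not pass by camera (adjusted p = 0.0571 to 0.861). Without sample 6 the number of lists was 2, and without samples 2 and 1 it was 5, of which 1 was shared with the 6. After GC and length correction the desmosome (camera adjusted p = 0.0551), immediate early (0.0551) and macrophage (0.158) lists did not pass.

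Relations between lists were then measured across the 9 samples, in 45 pairs of 10 list scores. The sarcomere and fatty acid oxidation scores rose together, with r = 0.96 (exact permutation p = 1.65e-05, adjusted p = 0.000744) and rho = 0.98 (exact permutation p = 4.96e-05, adjusted p = 0.00223). Without samples 9 and 6 the value was r = 0.99, within library sets r = 0.98, and in the 6 samples outside samples 3 to 5 r = 0.96. The sarcomere score also rose with nuclear oxidative phosphorylation (r = 0.87, exact permutation p = 0.0023, adjusted p = 0.0346; rho = 0.83, exact permutation p = 0.00827, adjusted p = 0.121). This relation had r = 0.82 without samples 9 and 6, r = 0.92 within library sets and r = 0.91 in the 6 samples. It did not pass after rescaling to the same total (r = 0.83).

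Oxidative phosphorylation and fatty acid oxidation had r = 0.90 (exact permutation p = 0.00168, adjusted p = 0.0346) and rho = 0.85 (exact permutation p = 0.00607, adjusted p = 0.121). Without samples 9 and 1 it was r = 0.61 (exact permutation p = 0.148), so this relation rests on those samples, while within library sets it was r = 0.90. When 1 sample was left out at a time, both relations of oxidative phosphorylation passed only without sample 3 or 5, with r of 0.79 to 0.89 for the sarcomere and 0.84 to 0.95 for fatty acid oxidation, and the relation of sarcomere and fatty acid oxidation passed in all 9 cases. The sarcomere and fibroblast scores had r = -0.83 (exact permutation p = 0.005, adjusted p = 0.0563) and rho = -0.80 (exact permutation p = 0.0138, adjusted p = 0.124), which did not pass. It was -0.71 without samples 9 and 6, -0.83 within library sets and -0.91 in the 6 samples, and after GC and length correction r = -0.84 passed (exact permutation adjusted p = 0.0438). The adipocyte score had r = 0.12 with the fibroblast score (exact permutation p = 0.745, adjusted p = 0.958; rho = 0.22, exact permutation p = 0.581, adjusted p = 0.90), r = 0.28 without samples 7 and 6 and r = 0.08 within library sets. The 3 library sets hold 2, 3 and 4 samples, so the within-set values are from scores with set means removed. There the smallest exact permutation p is 0.00347, or 0.156 after adjustment for a relation reaching it alone. A single relation could therefore not pass, and none did.

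**Figure D5:**
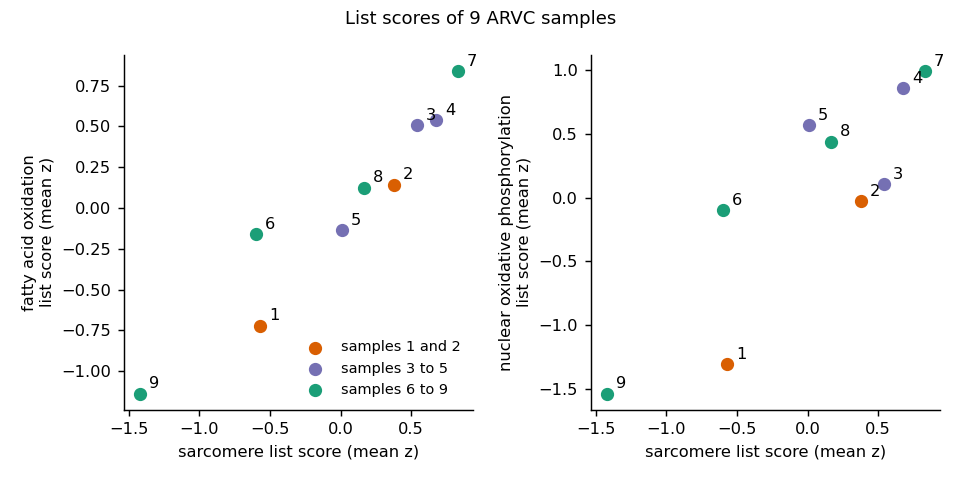
List scores of 9 samples (mean z of log2 values), with the sarcomere score on the horizontal axes and fatty acid oxidation (left) or nuclear oxidative phosphorylation (right) on the vertical axes, 1 numbered point per sample coloured by library set. The left pair has r = 0.96 and the right pair r = 0.87, and sample 9 is lowest in all 3 scores.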

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

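The family of values searched here was widened after a first set had been seen, so all of these values count as chosen after the result was seen. A value was picked out where the highest or lowest of 9 samples lay apart from its nearest neighbour by more than Dixon's 95% critical share of the whole range. Of 220 list scores and named genes, 11 were picked out, and chance alone picks out about 1 in 20. No explanation is offered for them.

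Sample 2 had the highest desmosome and intercalated disc list score, 1.484, against -0.852 to 0.167 in the others. Its DSC2, a desmosomal cadherin, was at 12.637 on the log2 scale (6368 normalised read counts), against 11.427 to 12.007.

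Sample 7, which had the lowest collagen score, was lowest in 3 of the genes that rose with that score. These genes were searched because they passed along that score, and sample 7 lay farthest from its median. The chance rate above therefore does not apply to them. F2R was at 10.931 against 12.045 to 13.122 in the other samples, MAP3K7CL at 8.004 against 9.309 to 10.633, and MFAP5 at 9.351 against 11.679 to 13.255.

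Sample 9 had the lowest CTNNA1, an adherens junction gene, at 14.447 against 14.781 to 15.017, and the lowest RPPH1 at 19.289 against 19.716 to 20.052. Its EBF2, a transcription factor of brown and beige fat cells, was highest at 12.342 against 10.734 to 11.482. Sample 1 had the highest IL6, an inflammatory cytokine, at 7.207 against 3.206 to 5.186. Sample 5 had the lowest LINC00657 at 14.923 against 15.441 to 15.834. Sample 8 had the highest OAS1, an interferon-induced gene, at 9.899 against 8.180 to 9.029.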

How the results depend on the processing

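The library sets, the GC and length correction and the 6 samples outside samples 3 to 5 were chosen after seeing the data. No paired analysis was possible because the labels give a single group. No named gene slope, pair ratio or named correlation reversed its direction. With the library sets as a covariate, medians of 3 lists called along the adipocyte score changed sign and no longer passed: desmosome (-0.13 to 0.036), macrophage (0.10 to -0.10) and nuclear oxidative phosphorylation (0.08 to -0.013). Of 4 lists passing there 2 were shared. Where a count moved, the cause was not tested, apart from fewer samples or fewer genes in some settings.

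Of the genes following the adipocyte score, 32 in the planned test, 3 passed with total reads as a covariate, 7 without the 2 samples farthest from the median, 11 with the library sets as a covariate and 93 by DESeq2. Leaving out each sample gave 17 (without sample 8) to 35 (without sample 7), with 20 without sample 2. Other settings gave 25 to 36. Its lists, 5 by camera, were 9 without the 2 farthest samples (3 shared), 3 in the 6 samples, 1 with an estimated correlation and 1 by fry, and 4 to 9 (without sample 9) on leaving out each sample.

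Of the genes following the collagen score, 9 in the planned test, 25 passed with a pseudocount of 8, 1 with no filter, 26 with a mean of at least 100, 35 after rescaling to the same total, 4 with COL1A1 alone as the score (0 of them shared), 1 by edgeR, 210 by DESeq2, 0 without the 2 farthest samples, 52 with the library sets as a covariate, 41 after GC and length correction and 0 in the 6 samples. Leaving out each sample gave 1 (without sample 1, 3, 5, 7 or 9) to 14 (without sample 2), with 2 without sample 6 or 8. Its lists, 9 by camera, were 1 with an estimated correlation, 1 by fry, and 7 to 13 on leaving out each sample.

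Natriuretic genes, 0 in the planned limma test (856 at an unadjusted p under 0.05) and by edgeR, were 18 by DESeq2 and 0 to 1 (without sample 1) on leaving out each sample. Its lists, 6 by camera, were 9 after rescaling to the same total, 7 with the library sets, 5 without the 2 farthest samples (1 shared), 3 after GC and length correction, 0 with an estimated correlation and 0 by fry, and 2 (without sample 6) to 8 on leaving out each sample. Of the correlations, 3 in the planned test, 1 to 3 passed on leaving out each sample (1 without any of samples 1, 2, 4, 6, 7, 8 and 9). With library set means removed 0 passed, and 0 in the 6 samples, but few orders exist there. The smallest exact permutation p, reached by 1 relation alone, would be 0.156 and 0.0625 after adjustment, so it could not pass. The spread count stayed at 14 to 20 lists over all settings and the paired ratios at 7 to 8.

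Over the named genes and relations, 294 of 311 alternatives for the adipocyte score, 173 of 288 for the collagen score, 138 of 144 for the natriuretic score, 30 of 51 for the correlations and 97 of 99 for the pairs stayed on the same side of the threshold. Of the collagen values, 107 no longer passed.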

Other observations

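All tests of explanations in this part were chosen after the result was seen. Marker genes of cell types other than muscle, fat and fibroblasts were also detected in the 9 samples. Endothelial genes were led by VWF at 69936 ± 17916 normalised read counts (SD, n = 9) and pericyte and smooth muscle genes by RGS5 at 35716 ± 9235, while MYH11, the smooth muscle myosin, ranged from 7555 to 59901. Macrophage genes were led by CD163 at 4585 ± 1559 and MRC1 at 3720 ± 1584, the mast cell gene KIT was at 831 ± 194, and the Schwann cell gene CDH19 at 10310 ± 3462. Lymphocyte genes were low, with CCL5 at 493 ± 200, and the B cell gene MS4A1 reached 181. HBB, the red cell globin, ranged from 1847 to 8416, and TOP2A, a gene of dividing cells, from 19.2 to 471.

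The genes that varied most within the library sets were ranked after seeing the data, and some of the first 12 are given here. DLK1, an imprinted gene of fat cell precursors, ranged from 1.30 to 825 normalised read counts, with an SD of 2.96 on the log2 scale within sets. COMP had an SD of 2.31, the fetal troponin TNNI1 of 1.95 (255 to 13630), ACTG2, a smooth muscle actin, of 1.98 (64.8 to 2381), the incretin receptor GLP1R of 2.02 (9.72 to 992) and SCG2, a neuroendocrine granule protein, of 2.16 (at most 885). The atrial light chain gene MYL4 ranged from 376 to 12743 and MYL7 from 2873 to 41406.

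Samples 3 to 5 differed from the other 6 in 1054 genes by limma, 915 of them lower. Of 313 genes nested inside a more expressed opposite-strand gene, 186 were lower and 0 higher. Of 11454 free genes, with no opposite-strand gene among those analysed, 2.69% were called in either direction. MIF was in this last class, so the class is not clear of genes split between the sets. Lower depth is argued against, since the lowest of the other samples, shallower ones included, had 5.22 nested reads per 10000, and so are GC content and length, since the nested genes stayed -2.94 (log2) from the free ones after correction. Only 1 of 84 splits into 3 and 6 samples, the real one, gave as many genes (highest other 103), but the samples were picked on these reads. Reads assigned by strand in samples 3 to 5 and without strand in the others may explain the nested difference of -3.13, but this set was defined by the same reads, and 36 genes with overlapped exons, where a rise was looked for, had a median of -1.93 with 20 below -1 and 8 above 1, so it cannot be told apart from other differences in library making or counting. The labels name 1 kit for all samples, so this explanation would need samples 3 to 5 to have been made or counted otherwise. No biological explanation was tested.

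The adipocyte list followed the adipocyte score with a median slope of 1.56. With the library sets in the model it was 1.55, and after GC and length correction 1.54, which argues against either as the whole cause, although 11 genes in place of 32 then passed with the sets. Of 100 orders of the score 2 gave as many genes, the real one included, a share under 0.05 that was not adjusted over the scores. The highest other order called 536, several times the real count, as a structure of the samples that was not traced could give. Within the sets 4 of 100 gave as many (highest other 11). The number of genes called therefore does not exclude chance. Outer fat of the heart carried with the tissue piece may contribute. Mesothelial and epicardial genes had a median slope of -0.20, but members ran from -0.72 to 1.71 (CALB2). Of the 9 members 1 rose and 0 fell over all genes tested, so their median decides nothing and this explanation stays open. The design names no group, and no biological explanation was tested.

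Fibroblast genes outside the collagen score followed it with a median slope of 0.53. If the share of cardiomyocytes fell and the mix of other cells stayed the same, endothelial genes would rise with fibroblast genes. The fibroblast median exceeded the endothelial one by 0.55 (95% bootstrap interval over genes 0.41 to 0.63). This interval treats genes as independent and holds no spread between samples. The difference goes against that case alone. A loss of muscle with unequal changes in other cells is not decided by it, and the sarcomere list had a lower median (-0.22). The fibroblast median was 0.56 after GC and length correction and 0.51 with the library sets in the model, so neither as modelled is its whole cause. The sets explained 1.39% of the variance of this score, so that model could change slopes on it little. The number of genes called did change, to 52 in place of 9. Of 100 orders 2 gave as many as 9 genes, the real one included, a share under 0.05 that was not adjusted over the scores. The highest other order gave 40, and within the sets 4 of 100 gave as many as the real order there (highest other 59). The number of genes called therefore does not exclude chance here either. Whether fibroblasts were more numerous or more active stays open, and no biological explanation was tested.

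For the natriuretic score limma called 0 genes (856 at an unadjusted p under 0.05, 0 by edgeR and 18 by DESeq2). Since no order can give fewer than 0, all 100 of 100 orders gave at least as many (highest other 2), so this comparison decides nothing.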
